A study of Mus musculus with 6 samples.

How the data were processed

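The series holds 6 samples of pancreas from KC mice: a 10x 5-prime gene expression library, a TCR library and a BCR library for the AB-680 group, and the same for the vehicle group. Per the labels' protocols, AB-680 was given by oral gavage at 10 mg per kg on 3 days a week, and tissue of 2 mice per group (4 mice in all) was minced, digested with collagenase and pooled before capture. The design therefore has 1 library per group and kind, called AB680 and Vehicle here, and the sex of the mice is not stated in the labels.

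The authors deposited UMI counts for 32285 genes in 25267 barcodes, made with Cell Ranger 7.0.0 per the submitters' processing notes, which also name the builds mm10 and GRCm38 without saying what each was used for. Per the names the authors gave the deposited tables, the counts had passed CellBender, which removes UMIs judged to be free RNA, and Seurat, with no settings stated. A deposited metadata table lists 13709 filtered cells with the authors' 17 cell classes and 41 clusters. That table also gives each cell's mitochondrial percent, as deposited by the authors, and a doublet score of scDblFinder per the file headers. Every listed cell is marked a singlet there. The listed cells have at least 218 UMIs and 201 genes, at most 14.3 mitochondrial percent, and a doublet score of at most 0.429. The TCR and BCR tables deposited by the authors give UMI and read counts per receptor contig, and every contig in them is marked high-confidence, full-length and productive.

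The filtered cells were used with the authors' classes. AB680 had 7433 filtered cells of 9187 barcodes, and Vehicle had 6276 of 16080. The quartiles of UMIs per cell were 1461 and 2954 in AB680 and 418 and 2874 in Vehicle, and the median cell had 1002 and 532 genes. After thinning each cell to 1000 UMIs, the median was 583 genes in AB680 and 580.0 in Vehicle, over 6761 and 3035 cells. Median mitochondrial percent was 0.870 and 1.20. Among the left-out barcodes, 714 of 1754 in AB680 and 8879 of 9804 in Vehicle had fewer than 1000 UMIs. The Scrublet method marked 1 AB680 cell and 0 Vehicle cells, a rate at which it cannot be said to have worked on cells already filtered by the authors' own caller. Barcodes that held both a TCR beta chain and a heavy chain were 0.135% and 0.127% of filtered cells, and they were kept.

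With 1 library per group there is no test across samples, and no p-value was computed. Shares of cells have exact Clopper-Pearson 95% intervals. UMIs of a gene were summed over the cells of a class and divided by the class total to give CPM, with exact Poisson intervals, and ratios have exact conditional intervals. All cover counting error only, and a sum of 0 was bounded with 3 UMIs. A ratio was called higher or lower when it passed 1.5 in that direction. The authors' clusters were checked against 30 fixed marker classes over the 10 top genes by fold, and ranked genes and gene lists were compared between groups only in classes with at least 100 cells in each library, over clusters that did not carry more markers of another class than of their own. The levels of adenosine genes are given for whole classes, including clusters outside this rule and classes with fewer cells. The rule left B mature, B prolif, Cd4 Th, Cd4 Treg and Cd8 T. The sums used 3159 and 1073 mature B cells, 127 and 259 dividing B cells, 1328 and 519 Cd4 Th cells, 424 and 169 Cd4 Treg cells, and 829 and 489 Cd8 T cells, AB680 named before Vehicle. For comparisons at equal depth each cell was thinned to 1000 UMIs, which left out 311 and 37 mature B cells, 4 and 122 dividing B cells, 45 and 29 Cd4 Th cells, 30 and 4 Cd4 Treg cells, and 0 and 2 Cd8 T cells.

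Genes are named by a rule of size. Of the genes with at least 50 UMIs over both libraries, at least 100 CPM in the higher library and a UMI in at least 5% of its cells, the rule takes the 10 with the highest and the 10 with the lowest ratio, after 0.5 UMI was added to each sum. Immunoglobulin and TCR segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes, predicted gene models and acinar enzymes were left out of that ranking. Members of 36 fixed gene lists, the adenosine genes and the marker genes are also named. A list needed at least 3 members with at least 20 UMIs over both libraries. Its median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of like mean expression. The marker classes, gene lists, naming rule, size rule and main alternatives were fixed before the data were examined.

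Clonotypes are those of Cell Ranger, and a clonotype was called expanded from 2 cells. The heavy chain with most UMIs gave a cell's isotype. Receptors and expression were joined by barcode within a group. Clonotype numbers were rarefied to the smaller library.

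The functions for sums, intervals and list percentiles were checked on Poisson counts simulated from the real means and depths. Such counts hold no spread between cells, clones or mice. The check therefore covers the computation under counting error only, not the real comparison of pools. In the Cd8 T simulation over 9592 genes, intervals held the true ratio for 96.2% of values at a fold of 1.5 and 95.7% of unchanged values. There 92.6% of genes changed 2 times passed the size rule, and so did 6.40% of unchanged genes. In the Cd4 Treg simulation over 7387 genes these were 87.3% and 13.4%, so single genes near the rule are less certain there. Simulated lists of 15 genes with a ratio of 2 passed the 97.5 percentile in 20 of 20 runs in each class, and unchanged lists in 1 of 20 and 0 of 20.

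Alternatives changed 1 choice at a time. For shares they were the cells kept, the depth, the denominator, doublets, and clusters rebuilt from 2000 variable genes and 30 principal components at Leiden resolutions of 0.5, 1 and 2, with or without centring each library. For genes and lists they were edgeR TMM factors, DESeq2 size factors, a total without abundant gene families, the mean over cells, thinning, other UMI minimums and the summed CPM of a list. For receptors they were the clonotype definition, the cells kept, at least 3 UMIs per contig and larger minimum clone sizes. The rebuilt clusters at resolution 1, gene sums over every cluster of a class, leaving out the cell with most UMIs of a gene, the split by Xist and Y-linked UMIs, the receptor barcodes with at least 1000 UMIs, 1 cell per clonotype over all cells or within a class, expanded cells within each class, Nt5e in each cluster, the dividing B cells without T cells and Peak1 in left-out barcodes of other depths were added after the data had been seen. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Gene names and identifiers are those paired in the deposited tables.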

Results

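The study gave KC mice, whose pancreas carries a mutant Kras switched on by Pdx1-driven Cre, either AB-680 or its vehicle. AB-680 is a small molecule that blocks CD73, the cell-surface enzyme encoded by Nt5e that makes immunosuppressive adenosine from AMP. Pancreas cells of 2 mice per group were pooled before capture, and each pool gave a gene expression library, a T cell receptor (TCR) library and a B cell receptor (BCR) library. The 6 samples therefore hold 1 library of each kind per group, and no value below has a replicate or a test across mice. The AB680 expression library held 7433 filtered cells with 20295867 unique molecular identifiers (UMIs), and the Vehicle library held 6276 cells with 13782945 UMIs. The median cell carried 2027 UMIs in AB680 and 876 in Vehicle, a ratio of 2.31. In Vehicle 51.6% of filtered cells had fewer than 1000 UMIs, against 9.04% in AB680. Intervals are 95% intervals and cover counting error only. "Higher" and "lower" mean a ratio of at least 1.5 in that direction.

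The cell class comparison asks whether blocking CD73 goes with another makeup of the pancreas. Most filtered AB680 cells were B and T lymphocytes. The Vehicle cells held smaller lymphocyte shares beside large classes that the authors named PanIN, for the precursor lesion of pancreatic cancer, and M2-like macrophage, for a tissue-repair state. Those Vehicle classes were built of barcodes with few UMIs, and among cells with at least 1000 UMIs the lymphocyte shares of the libraries came close to each other. B lineage cells made up 52.5% of AB680 cells (exact interval 51.3 to 53.6) and 26.5% of Vehicle cells (25.5 to 27.7). T lineage cells made up 41.5% (40.4 to 42.6) and 22.4% (21.4 to 23.5). Among cells with at least 1000 UMIs the B lineage ratio of AB680 over Vehicle was 1.08 (1.01 to 1.15), and the T lineage ratio was 0.980 (0.918 to 1.05). Mature B cells were the largest class in AB680, with 48.3% against 19.9%, and their ratio was 1.21 in the deeper cells.

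Within the T lineage the balance of helper, regulatory and cytotoxic cells differed by less than the size rule. Cd8 T cells, the cytotoxic class, were 33.4% of AB680 T cells (31.8 to 35.1) and 41.8% of Vehicle T cells (39.2 to 44.5). Their ratio was 0.799 (0.722 to 0.886). Regulatory T cells (Cd4 Treg), which restrain other lymphocytes, were 13.7% and 12.0% of T cells, a ratio of 1.15 (0.956 to 1.38). Helper T cells (Cd4 Th) were 47.5% and 42.1%. The class of dividing B cells had a lower share in AB680, at 2.57% against 5.53% of all cells and 2.75% against 6.89% of the deeper cells. It was not purely B cells, since 27 AB680 (14.1%) and 21 Vehicle (6.05%) cells carried a TCR beta chain. Without those and cells with Cd3 UMIs the shares were 2.06% and 3.90%, a ratio of 0.527. The gap came from cluster 15, with 10 AB680 and 204 Vehicle cells, and cluster 32, with 0 and 58, which was led by V segments such as Ighv13-2 and by histone genes. Clusters 20 and 25 had higher shares in AB680, at 1.57% against 0.876% and 0.861% against 0.478%.

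The macrophage, PanIN and plasma cell shares were lower in AB680, and the size of these gaps followed the number of UMIs per cell. The authors' PanIN class held 64 AB680 cells (0.861%) and 1699 Vehicle cells (27.1%), so its share was 31.4 times lower in AB680 (24.5 to 41.0). The 1699 Vehicle barcodes had a median of 377 UMIs, and only 5 of them reached 1000 UMIs, against 23 in AB680. Macrophages were 1.39% of AB680 cells and 9.56% of Vehicle cells, 6.90 times lower (5.59 to 8.59). Among cells with at least 1000 UMIs each library held 84 macrophages, and the share was still lower in AB680, 2.23 times (1.63 to 3.05). Antibody-secreting plasma cells were 0.848% and 3.0%, but 0.932% and 0.988% of the deeper cells. The authors' M1-like macrophage class, named for an inflammatory state, went the other way. It held 44 AB680 cells (0.592%) and 23 Vehicle cells (0.366%), a ratio of 1.62 (0.954 to 2.80) that fell to 0.859 in the deeper cells. All lay in cluster 30, led by Chil3, Adgre4 and Ace, with 0 macrophage markers and 1 monocyte marker among its 10 top genes. Neutrophils were 0.874% in AB680 and 0.366% in Vehicle, but their log2 ratio turned to -0.33 in the deeper cells. The M2-like class of Vehicle came mainly from clusters 17, 18 and 23, with 194, 191 and 111 of its cells. Monocyte genes such as Ccr2 and Fn1 were among the top genes of the former pair. Those of cluster 23 were Ccl8, Hmox1, the platelet factor gene Pf4, and Gas6 and Folr2 of the fixed tissue-resident macrophage list, among others. Genes inside these classes were therefore not compared between groups.

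**Figure D1:**
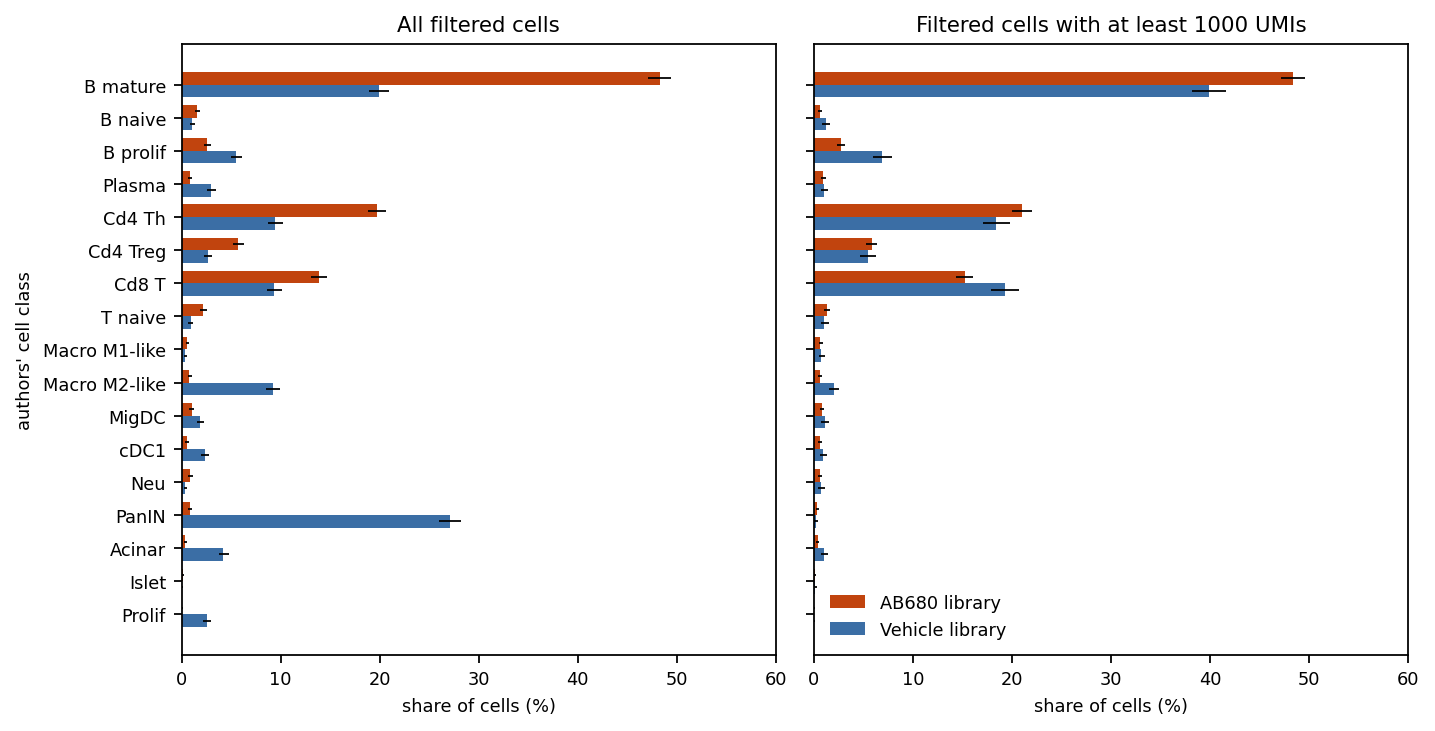
Bars give the share of cells (%) in each of the authors' 17 classes for the AB680 and Vehicle libraries, with exact 95% intervals, in all filtered cells (left) and in cells with at least 1000 UMIs (right). The PanIN bar of Vehicle stands at 27.1% on the left and all but vanishes on the right, where the mature B cell bars move closer together.

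The Cd8 T cell comparison asks how gene activity in the larger clusters of this class differed between the libraries. Type I interferon response genes, which cells switch on when they sense interferon alpha or beta, were lower in the AB680 Cd8 T cells. All 12 measured members were lower, with a median log2 ratio of -1.23 (interval -1.42 to -1.01), below all 10000 random lists of like expression. Lists of killing, exhaustion and quiescence genes had medians close to a ratio of 1 in the compared clusters. The compared cells came from clusters 1 and 12, with 829 AB680 and 489 Vehicle cells. The marker rule left out cluster 11 of this class, led by the effector genes Xcl1, Ccl5 and Ccl4, with 202 AB680 and 100 Vehicle cells. Killing and exhaustion genes were therefore not compared in that cluster. In the compared clusters the naive and memory list summed to 3860 CPM in AB680 and 3996 in Vehicle, and the cytotoxic list to 1288 and 1337 CPM. The values are thus not those of the effector cluster. Cluster 12 held 89 of the AB680 and 207 of the Vehicle cells. The type I interferon list was lower within clusters 1 and 12 alike, with ratios of 0.491 and 0.443. Isg15 (ENSMUSG00000035692), a ubiquitin-like protein induced by interferon, had 33.8 CPM in AB680 and 111 in Vehicle, 3.29 times lower (2.59 to 4.21). Ifi27l2a (ENSMUSG00000079017), a mitochondrial interferon-induced protein, had 279 against 609 CPM, 2.18 times lower (2.00 to 2.39). Oas1a, a sensor of double-stranded RNA, was 3.23 times lower, and Usp18, which removes Isg15 from proteins and damps interferon signalling, 2.78 times lower. Irf7, the transcription factor that amplifies interferon production, was 2.22 times lower. Both libraries held cells with Xist, the X-inactivation RNA of female cells, and cells with Y-linked UMIs. The list's ratio was 0.369 (0.332 to 0.410) in Xist cells and 0.899 (0.625 to 1.31) in Y-linked cells.

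Interferon gamma genes showed a smaller gap in Cd8 T cells. Their list had a median of -0.41, with 4 of 15 members lower, among them Socs1, a brake on cytokine receptors, at 52.6 against 96.2 CPM. Iigp1 and Igtp, GTPases that attack vacuoles of intracellular microbes, were 1.81 and 1.78 times lower. The cytotoxic list had a median of -0.00, with 8 of 19 members measured. The granule protein gene Nkg7 stood at 660 and 671 CPM and the pore-forming Prf1 at 40.4 and 34.7. The checkpoint list had a median of 0.10, with 5 of 13 members measured, and the naive and memory list 0.03. The T cell activation list stood at -0.47, with the growth regulator Myc at 37.6 against 65.2 CPM. Stress genes of tissue dissociation had a median of -0.51, within the size rule. Of 8 measured members 3 were lower, among them the immediate early genes Junb (1.82 times lower) and Ier2 (1.60 times lower). Ly6a, a stem cell antigen that interferon induces, was 1.95 times lower, and Sugct, a mitochondrial enzyme of glutarate metabolism, 1.80 times lower. Peak1 (ENSMUSG00000074305), a cytoskeletal pseudokinase, was 20.3 times higher in AB680 (14.1 to 30.3), and Auts2, a regulator of transcription, 1.67 times higher.

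**Figure D2:**
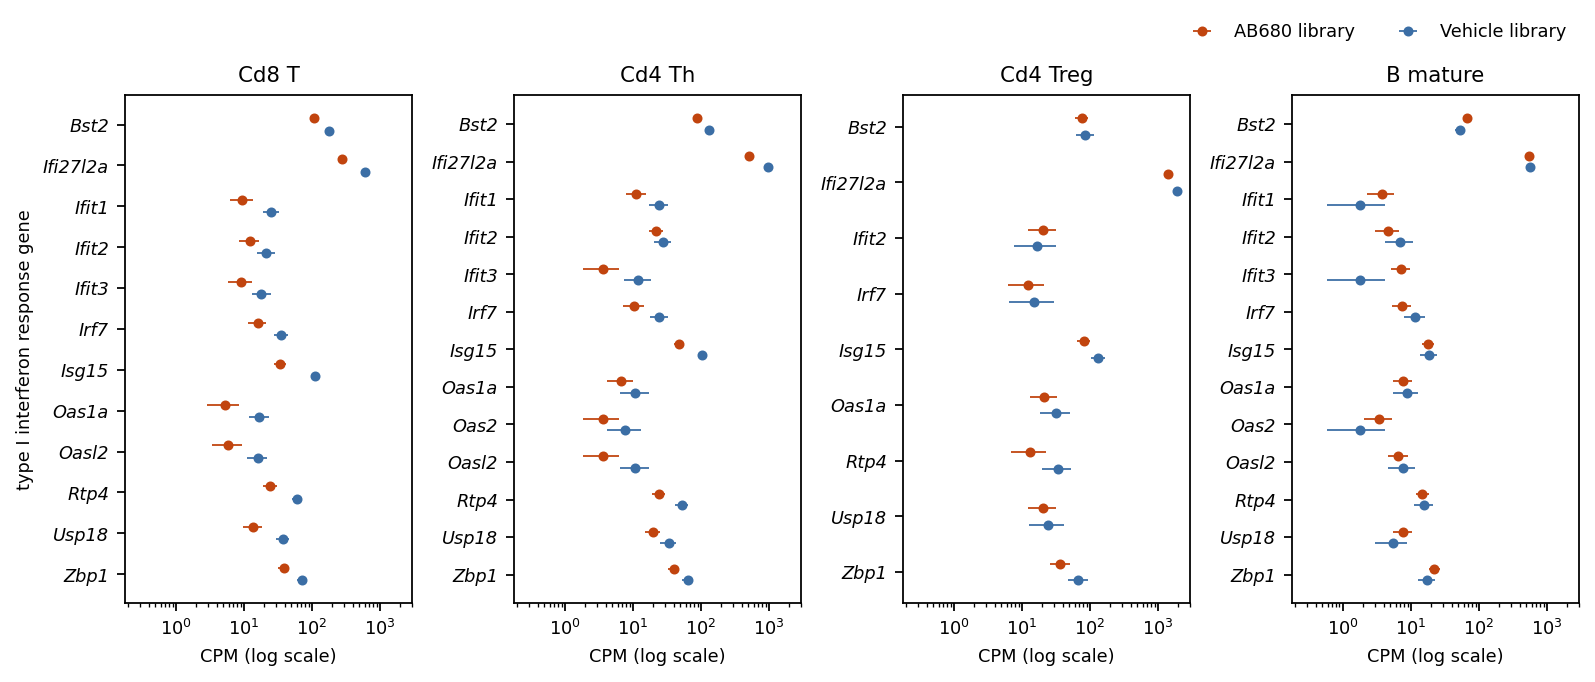
Points give CPM on a log axis for each measured type I interferon response gene in 4 cell classes, AB680 against Vehicle, with Poisson 95% intervals. In Cd8 T every AB680 point lies left of its Vehicle point (Isg15 at 33.8 and 111 CPM), and in mature B cells most pairs of points lie close together.

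The helper T cell comparison puts the same question to Cd4 Th cells. Type I interferon genes were again lower in AB680, for 11 of 13 members, with a median of -1.10 (-1.18 to -0.76), below all 10000 random lists. Their summed level was 795 CPM in AB680 and 1494 in Vehicle. Naive and memory genes were alike, with a median of 0.01. Most AB680 cells came from cluster 3 (853 cells) and most Vehicle cells from cluster 6 (403 cells), and the interferon list was lower in AB680 within each, 1.5 and 1.78 times. Isg15 was 2.22 times lower (1.78 to 2.78) and Ifi27l2a 1.93 times lower (1.80 to 2.07). Ifit3, an interferon-induced partner of proteins that bind viral RNA, was 3.30 times lower. Bst2, which tethers budding virus, and Ifit2 were between, at 89.3 against 131 CPM and 22.2 against 27.7 CPM. The type I list's ratio was 0.413 (0.372 to 0.458) in cells with Xist and 1.36 (0.983 to 1.91) in those with Y-linked UMIs. Interferon gamma genes had a median of -0.48, with 5 of 15 lower. Slfn1, which holds T cells in quiescence, was 1.87 times lower, and the interferon-induced GTPase gene Ifi47 1.75 times lower.

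A few metabolic and secretory genes of Cd4 Th cells were also lower. Unfolded protein response genes had a median of -0.44, with 4 of 9 lower. Glycolysis genes had -0.36, with 1 of 11 lower, and the enzyme Eno1 was 1.51 times lower. Oxidative phosphorylation genes had a median of -0.02, with 0 of 14 lower. Ass1, which makes arginine precursors, was 1.72 times lower, and Igfbp4, a growth factor binder of naive Cd4 cells, 1.52 times lower. Sugct was 2.29 times lower (2.02 to 2.59). Peak1 was 16.2 times higher in AB680 (10.8 to 25.5), and Gphn, the scaffold protein gephyrin, 1.72 times higher. Both were among the genes richest in the left-out Vehicle barcodes with few UMIs. The genes Tff1, Gkn1, Tff3 and Gkn2 of gastric mucus gave the Gastric and PanIN mucous list a median of 5.76, and all of their UMIs lay in 1 AB680 cell, 0.0753% of the class.

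The regulatory T cell comparison concerns the class with the most Nt5e among the larger T cell classes. Their interferon list had a median nearer 0, although the difference between classes was not tested, and genes that respond to cAMP, the second messenger raised by adenosine receptors, were lower as a list. The cAMP and CREB list had a median of -0.74 (-1.20 to -0.23), below all 10000 random lists, with 4 of 7 members lower and 1 higher. Its summed level was 357 against 465 CPM, a log2 ratio of -0.38 within the size rule. In Cd4 Th the list had a median of 0.16 and in Cd8 T -0.10. The T cell activation list, which shares Nr4a1, had a median of -0.29 in Cd4 Treg, with 4 of 11 lower. Whether adenosine signalling underlies these values was not tested. Crem, a cAMP-induced repressor, was 2.85 times lower and the nuclear receptor gene Nr4a3 2.83 times lower. Nr4a1, its relative induced by antigen receptor signals, had 31.6 against 52.7 CPM. Pde3b, which degrades cAMP, was 1.62 times higher. Type I interferon genes had a median of -0.44 (-0.81 to -0.21), with 4 of 9 lower. The comparison held 424 AB680 and 169 Vehicle cells of cluster 10.

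Genes that define regulatory T cell function were near a ratio of 1 or lower. Foxp3, their lineage factor, had 207 and 266 CPM, a ratio of 0.779. The Treg effector list had a median of -0.27, with the costimulatory receptor Tnfrsf18 at 208 against 324 CPM and Lrrc32, which displays latent TGF-beta, 1.85 times lower. The checkpoint list had a median of 0.25, where Ctla4, which strips costimulatory ligands from antigen-presenting cells, had 192 and 185 CPM. Il2rb, a chain of the interleukin-2 receptor, was 1.76 times higher (1.35 to 2.32) and Ccr7, which guides cells to lymph nodes, 1.87 times lower. Peak1 was 3.88 times higher (2.65 to 5.84) and Sugct 2.42 times lower. A single Vehicle cell held 66 of the 113 UMIs of Cd74, the class II chaperone, and without the cell with most UMIs in each library the log2 ratio of Cd74 in Cd4 Treg was -2.60. For the MHC class II presentation list in Cd4 Treg, leaving out such cells took the median from -2.09 to -0.40. The Cytotoxic effector list in Cd4 Treg moved from -0.59 to -0.17 in that way and to 0.34 after thinning. Of the 159 Vehicle UMIs of the granzyme gene Gzma, 158 lay in 1 cell.

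The mature B cell comparison asks the same of the largest class. Mature B cells had type I interferon genes at about the same level in the libraries, unlike the Cd8 T and Cd4 Th cells, although the difference between classes was not tested. Peak1 was far higher in AB680, and glycolysis genes had a median slightly below 0. The interferon list had a median of -0.06 (-0.11 to 0.36), with 719 and 728 CPM in sum. The compared cells lay in clusters 0, 2, 5 and 8, with AB680 cells mainly in clusters 0 and 2 and Vehicle cells mainly in clusters 0 and 8. Glycolysis genes had a median of -0.30, below all 10000 random lists, with 2 of 11 members lower, among them Gapdh at 397 CPM (1.51 times lower). Oxidative phosphorylation genes stood at -0.07. Ubb, a ubiquitin gene, was 1.55 times lower and Npc2, a lysosomal carrier of cholesterol, 1.61 times lower. Klf2, which keeps B cells quiescent and mobile, had 430 against 607 CPM, a ratio of 0.708 within the size rule. Sex-linked genes had a median of -1.02 in mature B cells, with 4 of 5 members lower, and cells with Y-linked UMIs were 87 of 2848 in AB680 and 84 of 1036 in Vehicle among those with at least 1000 UMIs.

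Lists of activation, secretion and antigen presentation genes had medians close to a ratio of 1 in the compared mature B cell clusters. The marker rule left out cluster 9, led by the activation genes Egr3, Il4i1 and Cd83, with 431 AB680 and 178 Vehicle cells. Activation genes were therefore not compared in that cluster. The B cell activation list had a median of -0.05, although Egr3, an early factor downstream of the B cell receptor, had 26.9 against 12.0 CPM. The plasma cell secretion list stood at -0.03 and the class II list at -0.06. Cr2, the complement receptor of follicular and marginal zone B cells, had 389 against 271 CPM, a ratio of 1.43 (1.32 to 1.56) within the size rule. Peak1 was 23.6 times higher (14.2 to 42.4), with a UMI in 11.2% of AB680 and 0.186% of Vehicle cells. In the left-out barcodes with fewer than 1000 UMIs, Peak1 had 1296 CPM in AB680 and 3628 in Vehicle, and in all left-out barcodes 309 and 1796 CPM. Camk1d, a calcium-dependent kinase, was 1.72 times higher, and Gphn had a ratio of 1.49, within the size rule. Both were, like Peak1, among the genes richest in the left-out Vehicle barcodes with fewer than 1000 UMIs, at 5784 and 50675 CPM there. The dividing B cells could be compared only across different clusters, since AB680 cells lay mainly in cluster 20 and Vehicle cells in cluster 15. Their proliferation list was alike, with a median of -0.05 and 10064 CPM in each library. Xbp1, the factor that drives antibody secretion, was 3.09 times lower there, and 72 of its 203 Vehicle UMIs lay in 1 cell.

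Antigen presentation by MHC class I, energy supply, NF-kB and dissociation stress had list medians within the size rule in the 4 large classes. MHC class I genes, which show peptides to Cd8 T cells, had medians between -0.15 (Cd4 Th) and -0.03 (Cd4 Treg and B mature). Oxidative phosphorylation genes lay between -0.09 and 0.00. The NF-kB list had a median of 0.16 in Cd4 Th, which turned to -0.082 after thinning, and -0.05 in Cd8 T. Transcripts of the mitochondrial genome had medians below 0 but within the size rule, at -0.40 in Cd8 T, -0.36 in Cd4 Th, -0.25 in B mature and -0.12 in Cd4 Treg. These medians lay at percentiles 0.02, 0.04, 0.17 and 14.7 of random lists, in the same order. Glycolysis genes had medians of -0.35 in Cd8 T (percentile 0.05) and -0.17 in Cd4 Treg (percentile 7.255), and dissociation stress genes -0.23 in Cd4 Treg (percentile 4.87). In Cd4 Th the latter stood at -0.33, but at 0.020 after thinning and 0.0046 as a mean over cells.

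**Figure D3:**
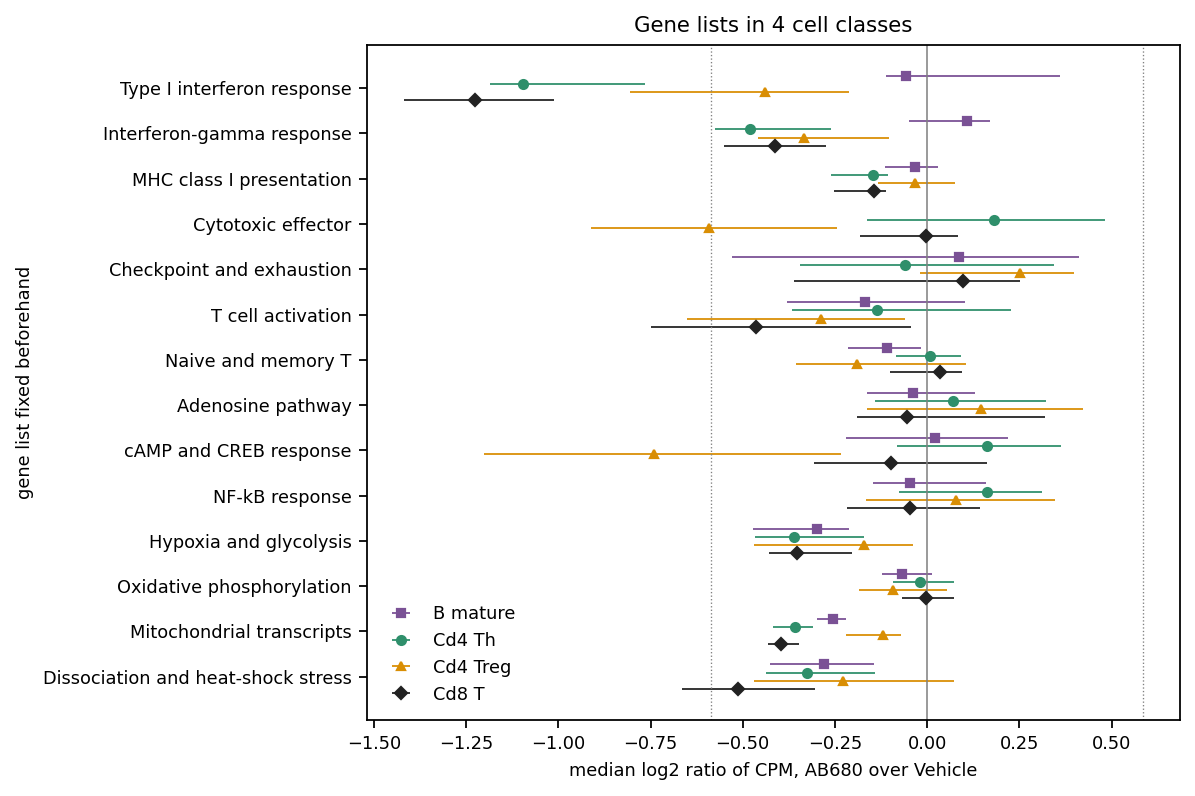
Points give the median log2 ratio of CPM, AB680 over Vehicle, of 14 gene lists in 4 cell classes, with intervals from counting error and dotted lines at a ratio of 1.5 in each direction. The type I interferon list lies at -1.23 in Cd8 T, -1.10 in Cd4 Th, -0.44 in Cd4 Treg and -0.06 in B mature.

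The drug target comparison asks which cells carry Nt5e and whether its RNA differed. Regulatory T cells and the class that the authors named naive T cells carried the most Nt5e (ENSMUSG00000032420). Cd8 T and helper T cells carried less, and mature B cells almost none. Within each T cell class the levels of AB680 and Vehicle differed by less than the size rule. AB-680 acts on the enzyme, so its effect need not show in the RNA. Regulatory T cells had 239 CPM (209 to 271) in AB680 and 217 (179 to 260) in Vehicle, a ratio of 1.10 (0.877 to 1.39). The naive T class had 225 and 151 CPM. It was cluster 14, with 0 of its own markers among its 10 top genes and median depths of 1091 and 1225 UMIs. A TCR beta chain was found in only 7.98% and 17.5% of its cells. Cd8 T cells had 50.0 and 49.9 CPM, and Cd4 Th cells 38.6 and 37.4. A UMI was found in 34.7% of AB680 and 38.5% of Vehicle regulatory T cells, at median depths of 2058.5 and 2759 UMIs, and in 18.02% and 19.4% after thinning each cell to 1000 UMIs. In mature B cells, which should lack it, the share was 0.306% and 0.160% at median depths of 1680.5 and 2364 UMIs. Dividing B cells as a whole class had 46.7 and 22.5 CPM, a ratio of 2.08 (1.40 to 3.16), but their clusters differed between libraries and the class held T cells. Without cells that had a TCR beta chain or Cd3 UMIs they had 33.7 and 9.69 CPM, a ratio of 3.48 (1.80 to 7.37), from 55 and 11 UMIs. With all cells, over the compared clusters 15 and 20 the ratio was 1.75 (1.13 to 2.77), within cluster 20 alone 1.64 (1.04 to 2.65), and within the germinal centre cluster 25 4.84 (1.47 to 25.1), from 24 and 3 UMIs. The PanIN class had 66.8 CPM in Vehicle (49.1 to 88.8), and 0 UMIs in AB680, which allows up to 52.7 CPM.

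Other genes of the adenosine pathway marked distinct cell classes, and as a list they differed little between groups. Entpd1 (CD39), which makes the AMP that CD73 uses, was strongest in neutrophils, with 702 CPM in AB680 and 656 in Vehicle. Cd38, which starts another route to adenosine, was strongest in the authors' naive B class (1006 and 688 CPM). That class had 0 B cell markers among its top genes. Dpp4, also a member of the adenosine list, was found in naive T cells (405 and 280 CPM) and migratory dendritic cells (376 and 394 CPM). Migratory dendritic cells also had the receptor gene Adora2a, at 111 CPM (74.7 to 158) in AB680 and 96.2 in Vehicle. The adenosine list had medians of -0.04 in B mature, 0.07 in Cd4 Th, 0.15 in Cd4 Treg and -0.05 in Cd8 T.

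**Figure D4:**
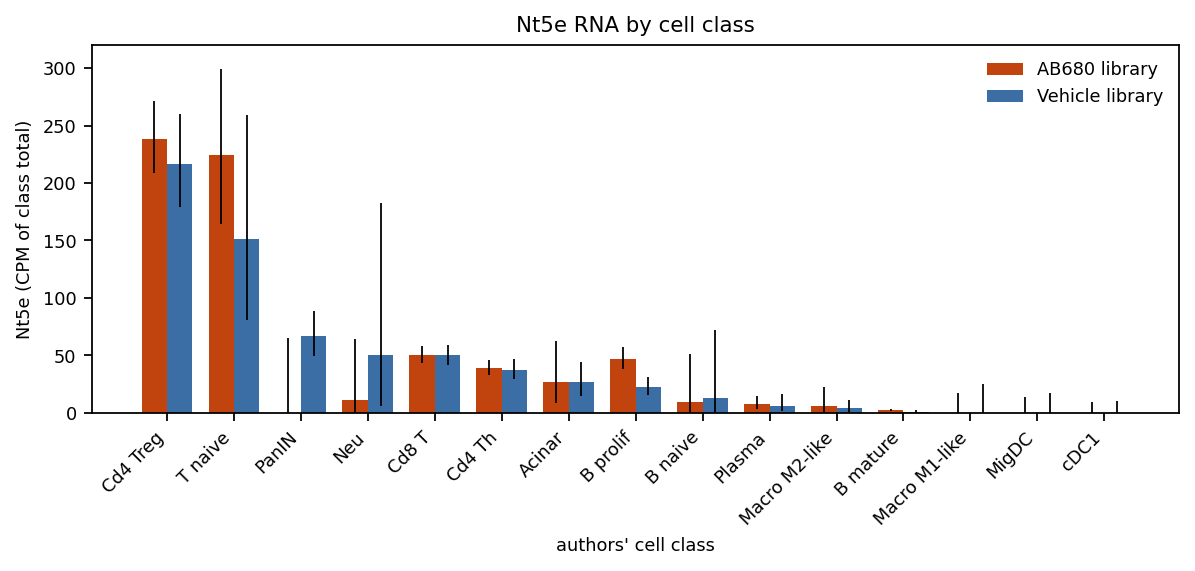
Bars give Nt5e CPM in the authors' cell classes for AB680 and Vehicle, with Poisson 95% intervals. Regulatory T cells stand highest among the classes in AB680 (239 and 217 CPM), and mature B cells lie near 0 (2.10 and 0.584 CPM).

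The TCR comparison asks whether T cells had multiplied from shared precursors. Clones were small in both libraries, and AB680, which had more cells sampled, held the larger share of T cells in clones of at least 2 cells. The AB680 library had 1747 cells with a TCR beta chain in 1719 clonotypes, and Vehicle had 1201 cells in 1191. Expanded clonotypes held 52 AB680 cells, 2.98% (2.23 to 3.89), and 19 Vehicle cells, 1.58% (0.955 to 2.46). The ratio was 1.88 (1.09 to 3.37), and the largest clones had 4 and 3 cells. The interval included 1 with clonotypes by TRB nucleotides (1.57, 0.964 to 2.62) or paired chains (1.41, 0.428 to 4.92), in the authors' filtered cells (1.89, 0.944 to 4.04) and with clones from 3 cells (2.29, 0.590 to 13.0). The expanded share rises with the number of cells sampled. Rarefied to 1201 cells, AB680 would show 1187 clonotypes, close to the 1191 of Vehicle. Regulatory T cells had the highest expanded share in AB680, 15 of 247 cells or 6.07% (3.44 to 9.82). In Vehicle 0 of 136 were expanded, which allows up to 2.68%. In Cd8 T cells 5 of 488 AB680 cells and 0 of 446 Vehicle cells were expanded. A beta chain was found in 46.3% of AB680 and 73.4% of Vehicle T cells.

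Expanded T cells of AB680 held more regulatory T cells than cells whose receptor was seen once, 15 of 38 against 232 of 1376, and regulatory T cells carried the most checkpoint RNA of these classes. Over the 3 large T cell classes together the checkpoint list had 1265 CPM (1057 to 1502) in expanded and 540.2 CPM in single cells. Within regulatory T cells it had 2733 (2242 to 3300) against 1896 CPM, and within Cd4 Th cells 269.9 (139 to 471) against 367 CPM. The 5 expanded Cd8 T cells had 10 such UMIs. Naive and memory genes had 2365 against 3430.4 CPM, and cytotoxic genes 2102 against 1749 CPM, over the classes together, which mixes classes in unlike proportions. Within classes the cytotoxic list had 1687 against 682 CPM in Cd4 Th, 7079 against 3283 in Cd8 T and 202 against 323 in Cd4 Treg. The naive and memory list had 3374 against 3847 CPM in Cd4 Th, 3194 against 3582 in Cd8 T and 835 against 1749 in Cd4 Treg. In Vehicle these classes held only 7 expanded cells. The most used beta chain V genes, among them TRBV1, TRBV3 and TRBV16, had ratios between 0.770 and 1.24.

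The BCR comparison asks the same of B cells and adds the antibody class. AB680 B cells carried almost as many different heavy chains as cells, whereas in Vehicle a few large clones of plasma and dividing B cells stood out. Heavy chains called IgD were more common in AB680 and those called IgM in Vehicle. Each cell was given 1 isotype, so a cell that carries both IgD and IgM counts under 1 of them. AB680 had 1778 cells with a heavy chain in 1758 clonotypes, and Vehicle 1321 cells in 1073. Expanded clonotypes held 34 AB680 cells, 1.91% (1.33 to 2.66), and 271 Vehicle cells, 20.5% (18.4 to 22.8). The largest Vehicle clones had 67, 65 and 58 cells, and the largest AB680 clone 4. They used IGHV5-4 with IgM, IGHV13-2 with IgM and IGHV1-54 with IgA. Most of their barcodes lay in clusters 33, 32 and 24, which held 0 AB680 cells, and their median RNA depths were 744, 1161 and 529.5 UMIs. Plasma cluster 26 had medians of 15728 UMIs in AB680 and 17352 in Vehicle. Whether each barcode of the large clones held a cell of its own was not tested. A clone of 16 cells with IGHV2-2 had 10 of its 11 filtered cells in the acinar class, and 14 of its barcodes had fewer than 1000 UMIs. In barcodes with at least 1000 UMIs of RNA the expanded share was 1.88% in AB680 and 7.87% in Vehicle.

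IgD chains were found in 56.6% of AB680 cells (54.3 to 59.0) and 29.7% of Vehicle cells (27.2 to 32.2), a ratio of 1.91 (1.70 to 2.15). IgM chains were found in 33.5% and 56.1%. IgA chains, which serve mucosal surfaces, were found in 4.92% and 7.84%, but the log2 ratio of -0.67 turned to 0.38 in barcodes with at least 1000 UMIs and to 0.10 with 1 cell per clonotype. Within mature B cells IgD made up 62.1% and 38.01% of chains. The RNA ratio of AB680 over Vehicle was 1.33 (1.27 to 1.39) for Ighd and 1.23 (1.19 to 1.27) for Ighm, both within the size rule. Ighm RNA thus did not follow the lower IgM share of AB680. Contig depth differed too, as 841 of 1778 AB680 cells and 979 of 1321 Vehicle cells had a heavy chain contig with at least 3 UMIs. IgA led among plasma cells, in 76.8% of those with a chain in AB680 and 51.9% in Vehicle, or 78.8% and 67.9% with 1 cell per clonotype. Dividing B cells carried IgM in 32.5% of chains in AB680 and 66.9% in Vehicle, but with 1 cell per clonotype in 34.3% (23.3 to 46.6) and 28.8% (17.1 to 43.1), since 1 clone held 58 of the 81 Vehicle IgM chains. IgG1 made up 21.4% and 48.1% of their chains with 1 cell per clonotype, against 19.5% and 21.5% over all cells. A heavy chain was found in 37.7% of AB680 and 54.9% of Vehicle cells of the B and plasma classes.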

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

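Thinning and the share among cells with at least 1000 UMIs were planned settings, the other tests in this part were chosen after the results had been seen, and every hypothesis here was found and tested on the same libraries.

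The Vehicle library held large classes of barcodes with few UMIs, above all the class that the authors named PanIN, with a median of 377 UMIs. Its ductal and gastric marker genes had 1.42 CPM in sum (up to 7.91), below the 4.96 CPM found in mature B cells, which argues against pancreatic epithelium as the content of this class. Across genes its profile resembled that of the left-out Vehicle barcodes with fewer than 1000 UMIs, with a Pearson r of 0.770 against a median of 0.620 over the classes (genes are not independent replicates). The Prolif and acinar classes came next, at 0.712 and 0.709. In AB680 the 64 PanIN barcodes had an r of 0.363 with the left-out AB680 barcodes, at rank 10 of the classes. For the Vehicle class, barcodes with little RNA of their own that passed the filter are a candidate explanation for the gap in the PanIN share. For the authors' macrophage classes the log2 ratio was still -1.16 (-1.61 to -0.70) among cells with at least 1000 UMIs. Among the 10 top genes, their clusters 17, 18, 23 and 30 carried more fixed monocyte or platelet markers than macrophage markers, on counts of 2, 2, 1 and 1 against 1, 0, 0 and 0. The top genes of cluster 23 also included Gas6 and Folr2, members of the fixed list of tissue-resident macrophage genes. Clusters 17, 18, 23 and 30 held 194, 191, 111 and 23 Vehicle cells against 2, 1, 1 and 44 AB680 cells. With so few markers it stays open whether the shares are of macrophages alone. With 1 pool per group, fewer macrophages under the inhibitor and differences in capture or between mice cannot be told apart.

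Type I interferon genes were lower in AB680 Cd8 T and Cd4 Th cells. Thinning each cell to 1000 UMIs left medians of -1.14 and -0.96. CPM is already scaled to depth, and thinning keeps the expected proportions of genes within each cell. It changes mainly the weight of each cell, so these medians do not decide whether depth plays a part. In cells with Y-linked UMIs the ratio was 0.899 (0.625 to 1.31) in Cd8 T, 1.36 (0.983 to 1.91) in Cd4 Th and 0.739 (0.496 to 1.10) in Cd4 Treg, and the upper bounds in cells with Xist were 0.410, 0.458 and 0.845. These intervals cover counting error in 1 pool per group, with 14, 17 and 10 Vehicle cells with Y-linked UMIs, and leave out the spread between mice. Within each library the list's CPM in cells with Xist was also set against that in cells with Y-linked UMIs. This ratio was 1.86 in Vehicle and 0.762 in AB680 for Cd8 T, and 1.87 and 0.565 for Cd4 Th. For Cd4 Treg it was 1.47 and 1.52. Cells with Xist and with Y-linked UMIs thus differed within a treatment too, in opposite directions between the libraries for Cd8 T and Cd4 Th. An effect of the inhibitor alike in both sexes and a difference between the pooled mice therefore cannot be told apart. An effect limited to cells of 1 sex stays open.

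The interferon list in Cd4 Th also stood out by its log2 ratio of 0.45 (-0.025 to 0.93, which includes no change) in cells with Y-linked UMIs, against -1.28 in cells with Xist. In mature B cells it was 0.35 (0.043 to 0.66) with Y-linked UMIs and -0.092 with Xist. In dividing B cells, whose clusters differed between libraries, it was 2.25 (1.89 to 2.61) and -0.85. The intervals cover counting error only, and these differences between sexes were not tested across mice.

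Peak1 was higher in AB680 in each of the 4 large lymphocyte classes. Its CPM in left-out barcodes was lower there, with ratios of 0.357 (0.314 to 0.405) below 1000 UMIs and 0.761 from 1000 UMIs, but the counts had passed CellBender and do not measure free RNA, so a higher share of Peak1 in the free RNA of AB680 and none cannot be told apart. The other 19 genes richest in the left-out Vehicle barcodes with fewer than 1000 UMIs, Gphn and Camk1d among them, also shifted upward in AB680 cells. Their median log2 ratios were 0.45 in B mature, 0.42 in Cd4 Th and 0.50 in Cd8 T, each above all 10000 random lists. Only 7, 8 and 6 of them were higher, and 2, 2 and 3 lower. In Cd4 Treg their median was 0.10, at percentile 92.3 of random lists, which is too near chance for a shared shift and none to be decided, so they cannot be told apart, and in dividing B cells, whose clusters differed between libraries, it was -0.43, with 0 higher and 7 lower. A candidate explanation is a shift of such genes that processing left in the kept cells of 1 library, although the shift of the list is far smaller than that of Peak1, and an effect of the inhibitor on Peak1 itself stays open.

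Receptor contigs also appeared outside the filtered cells. Of the cells with a TCR beta chain, 273 of 1747 in AB680 and 122 of 1201 in Vehicle were barcodes outside them, and of those with a heavy chain 272 of 1778 and 259 of 1321.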

How the results depend on the processing

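The settings named as added were chosen after seeing the data, and the others were planned. Values are log2 ratios of AB680 over Vehicle. Of 2425 alternative values over 277 results, 2160 stayed within the main interval, 231 moved beyond it and 34 reversed. For lists these were 1326, 103 and 20 of 1449, and for genes 746, 72 and 6 of 824. Some settings could change little by construction, so the count of unchanged values is no measure of robustness. The largest shift by TMM or DESeq2 factors was -0.060, in Cd4 Th, and the doublet setting left out 11 AB680 and 8 Vehicle cells. The type I interferon list stayed past the size rule under every scaling, filter, thinning and averaging tried in Cd8 T and Cd4 Th. In Cd4 Treg it stayed below 0.

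Shares of cells depended most on the processing. With only cells of at least 1000 UMIs the B lineage went from 0.98 to 0.11, the T lineage from 0.89 to -0.029, macrophages from -2.79 to -1.16 and PanIN from -4.97 to 1.05. M1-like macrophages went from 0.69 to -0.22 there, and neutrophils to -0.33. This setting removes the shallow Vehicle barcodes by construction. As a share of immune cells the B lineage gave 0.41, the T lineage 0.31 and macrophages -3.36, since the PanIN class leaves the denominator. With every barcode of at least 500 UMIs and 300 genes the values were 0.53 for the B lineage, 0.60 for the T lineage, -2.35 for macrophages and -5.87 for PanIN. Clusters rebuilt at Leiden resolution 1 (added) gave 1.19 for the B lineage, 0.77 for the T lineage and -2.85 for PanIN. At resolution 0.5 they gave 0.77 and 0.78 for the lineages and no PanIN cluster, and at resolution 2 they gave 1.18, 0.72 and, for PanIN, -2.69. After centring each library the B lineage gave 1.14, PanIN -2.95 and Treg of T cells 0.47. For these the cause was not tested.

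Within dividing B cells, whose clusters differed between libraries, the mean over cells gave Slc41a2 -0.17, Atxn1 -0.59 and Eaf2 0.15. It gave the checkpoint list 0.25, plasma cell secretion 0.16, acinar enzymes -0.80, glycolysis 0.010 and the unfolded protein response 0.0071. Thinning gave Sox5 -0.059, Pdzd2 -0.031 and Man2a1 -0.78. Without the cell with most UMIs (added) the checkpoint list gave 0.10, T cell activation 0.16 and acinar enzymes -0.25, and by summed CPM the naive and memory list gave 0.26 and the sex-linked list 0.65. In mature B cells the acinar list went from -0.57 to 0.43 thinned, 0.64 with at least 100 UMIs per gene and 0.39 by summed CPM, the sex-linked list from -1.02 to 0.20 by summed CPM, and the type I interferon list -0.22 thinned. In Cd4 Th the dissociation list gave 0.020 thinned and 0.0046 as a mean over cells, and the NF-kB list -0.082 thinned. In Cd4 Treg the cytotoxic list gave 0.34 thinned and T cell activation 0.25 with at least 100 UMIs per gene. The cause was not tested for any of these.

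The split of the summed type I interferon CPM by sex-linked UMIs (added) gave -1.44 in Cd8 T and -1.28 in Cd4 Th cells with Xist, and -0.15 and 0.45 in those with Y-linked UMIs. Among receptors the expanded BCR share gave -2.06 in barcodes with at least 1000 UMIs (added). Shallow barcodes are left out there, and Vehicle kept 11 expanded clonotypes with 86 cells, the largest of 48. IGHD gave 1.22 with at least 3 UMIs per contig and 0.66 with 1 cell per clonotype (added). IGHA gave 0.38 with at least 1000 UMIs, where shallow barcodes are left out, and 0.10 with 1 cell per clonotype, where each clone counts once (both added). In that way IGHM gave 0.25 in dividing B cells and 0.11 in plasma cells. The TCR expanded share gave no value from 5 cells, as no clone was that large. Median depth gave 2.47 over every barcode. Classes with under 100 cells in a library, such as plasma cells and dendritic cells, had no gene comparison.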

Other observations

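The values in this part were picked after the results had been seen and come with no explanation. The authors' clusters held small lymphocyte states that their class names do not show. Cluster 25 carried germinal centre genes, namely Aicda, which mutates antibody genes, Rgs13 and S1pr2, which confine cells to the follicle. It held 64 AB680 and 30 Vehicle cells, which gave a ratio of 1.80 (1.15 to 2.88) as shares of all cells and 0.912 (0.582 to 1.46) as shares of the B lineage. Cluster 11, within the Cd8 T class, was led by the chemokine genes Xcl1, Ccl5 and Ccl4 and by killer cell lectin receptors such as Klre1, and held 202 and 100 cells. Cluster 16, within the Cd4 Th class, was led by the gamma-delta receptor gene Tcrg-C1, the tissue homing receptor Cxcr6 and the granzyme Gzmk, and held 138 and 74 cells. Cluster 9, within the mature B class, was led by Egr3, Il4i1, Cd83 and Mir155hg, genes of antigen-activated B cells, and held 431 and 178 cells.

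Stromal and gut epithelial genes appeared under immune and acinar names. Cluster 22, placed in the cDC1 class, was led by the fibroblast genes Dcn, Fbn1 and Col3a1 and held 4 AB680 and 122 Vehicle cells. Cluster 37, placed in the acinar class, was led by Tff1 and Gkn1 of gastric mucosa and Prap1 of the gut, and held 12 and 20 cells. Adenosine deaminase, encoded by Ada and able to remove the product of CD73, had 2492 CPM in the Vehicle acinar class, all from 8 of its 265 barcodes. The 28 AB680 cells of that class had 0 Ada UMIs, which allows up to 16.1 CPM.

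Identical receptor sequences of both groups were mainly kappa light chains. Kappa light chains shared 391 V gene and CDR3 sequences between AB680 and Vehicle, heavy chains 16, lambda chains 12, TCR alpha chains 2 and TCR beta chains 1. Kappa was the light chain in 93.7% and 96.0% of cells. The heavy chain V gene IGHV9-3 was used by 4.33% of AB680 and 2.42% of Vehicle cells, a ratio of 1.79.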
